A study of Mus musculus with 7 samples.

How the data were processed

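The data were ac4C RNA immunoprecipitation sequencing libraries of wild-type mouse, labelled as ovary: 3 ac4C IP libraries, 3 Input libraries with the same replicate numbers and 1 IgG library. Per the labels' protocols, polyadenylated RNA was used, and libraries were made by a Smart-seq2 type of amplification and tagmentation, which keeps no strand. The series' design text also speaks of isolated oocytes and of a conditional Nat10 knockout; no knockout library was used here, so a targeted gene could not be checked. Groups and replicate numbers were taken from the sample titles.

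The 6 files were lists of enriched sites, each made from 1 IP library and 1 control library and not from pooled samples. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10a, and featureCounts and the mm10 genome were used. The columns have the form that MACS writes; the peak caller's version and its scaling of libraries are not given in the sources used here. In the deposited lists the score of a site equals the column of log-transformed p-values in every row, with a lowest value of 50. Fold enrichment is the authors' ratio of IP over control at the site, with a lowest value of 2.00 against Input and 3.68 against IgG. The false discovery rate is given by the authors in percent. The sites' numbers run up to 191399 in a list that holds 47573 of them, so the lists are a part of the called peaks, chosen by the authors by a rule not given in the sources used here. Sites carry a gene name but no exon, UTR or strand.

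The design fixed before the data were examined allowed for read counts. The files held called sites only, so no count model was fitted, and the plan for the authors' own calls was followed: a gene was called in a list when it had a listed site. An ac4C gene had a site in all 3 lists against Input and all 3 against IgG. The strongest site stood for a gene in each list, and its log2 fold was averaged over 3 replicates with the SD. Folds printed for a gene are 2 to the power of that mean. Sites of 1 gene were shared when they overlapped by at least 1 base, with 50% of both sites as the alternative. Coordinates are on mm10 and count from 1.

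Gene lists were fixed before the data were examined: 15 lists of oocyte, maternal effect, meiotic, mRNA decay, translation, ribosomal, mitochondrial, RNA modification, chromatin and signalling genes, and of markers of granulosa, theca, stromal and muscle, and endothelial, immune and epithelial cells. Some genes stand in more than 1 list. Membership was tested against calling with Fisher's exact test, two-sided, over the 14625 genes named in any list, with Benjamini-Hochberg adjustment over the 15 lists. Since the lists hold only called sites, genes with no site in any list could not enter the background. After the data were seen, permutation tests of list membership were added, two-sided, in which 10000 random lists were drawn that matched each list on genomic gene length in 10 bins, on a derived Input level in 5 bins, or on the number of sites for the comparison of folds; the smallest p they can give is 0.0002 before adjustment. The derived Input level is the fold over IgG divided by the fold over Input at identical intervals where IgG was at its lowest value. Its rank correlation between replicates was 0.756 to 0.757 across 7864 genes. It is linked to the fold over Input by construction, and it is an upper bound at sites where Input was at its own lowest value. Gene lengths and coordinates came from the RefSeq table of the same assembly, in which 14079 of 14235 gene IDs were found, and 97.2% of the sites lay inside their RefSeq gene. Lengths of mature mRNAs were not used here.

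The lowest value of the control side, IgG or Input, was found as the step whose whole multiples held most folds (tolerance 0.0075). A first, coarser estimate of the step misplaced large folds: with the step against IgG rounded to 4 decimals, 96.3% to 99.6% of the sites in the highest of 10 score bins came out off the step. The step was therefore refined by least squares over growing ranges of fold before its values were used.

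Genes named in the text followed a rule fixed before the data were examined: the 10 genes with the largest mean log2 fold over Input among ac4C genes, the 5 with the most sites, from each list the 2 ac4C genes with the largest mean log2 fold and the 1 other member found in the most lists, and Nat10, Gdf9, Zp3 and Bmp15; predicted gene models were left out of the first 2 groups. A gene that the rule takes is not reported here. Further list members are named only by their calls and were chosen after these were seen.

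Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. Fisher's exact test was run over 15 simulated lists of the real sizes, drawn from 14080 genes. It found 93.8% of 5 lists with a share raised to 93% and passed 1.4% of the others. Smaller differences in share were not simulated, so the power for them is unknown. In lists of 40 long genes called by length alone, the length-matched test passed 5.0% and Fisher's exact test 23.0%. Rotation of sites found shared positions in 100% of simulations with them and 0% without, over 2000 genes. Simulations without them were made by the same random rotation that the test draws, so their low rate was given by construction. Edges of genes were not simulated. Alternatives covered a stricter score or fold, a lower false discovery rate, fewer replicates, the overlap rule and the background of the list tests.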

Results

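N4-acetylcytidine (ac4C) in mouse RNA was mapped by immunoprecipitation of acetylated RNA fragments followed by sequencing. NAT10, the acetyltransferase that makes ac4C, is the enzyme the series is about, and all 7 libraries analysed here came from wild-type mice, with ovary as the labelled tissue. They were 3 ac4C immunoprecipitation (IP) libraries, 3 Input libraries that carry the same replicate numbers, and 1 library made with non-specific IgG. The values used were 6 lists of enriched sites, 1 for each IP replicate against its own Input and 1 for each IP replicate against the shared IgG library. Fold enrichment, score and false discovery rate are the authors' own values for each site. The depth of the single libraries is unknown from these lists, so no counting interval can be given for a site. Nothing in the labels says that replicates were separate animals, so the spread between them may be technical.

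The first comparison asked which RNAs were enriched in the ac4C IP over Input. Among genes with sites in all 6 lists, the largest enrichment belonged to Hist1h2af, a histone H2A gene, whose strongest site was 2047-fold over Input (SD of the log2 fold 0.32, n = 3). Histone H2A genes made up 4 of the 10 largest, with Hist1h2ab at 1523-fold, Hist1h2ao at 1426-fold and Hist1h2ai at 1012-fold. The others were Polr2a at 1499-fold, Nudc at 1269-fold, Atn1 at 1241-fold, Syncrip at 1030-fold, Mfap2 at 935-fold and Nufip2 at 902-fold, with SDs of the log2 fold between 0.27 and 0.62 (n = 3). Polr2a encodes the largest subunit of RNA polymerase II, Syncrip an hnRNP-family RNA-binding protein, and Mfap2 a microfibril protein of the extracellular matrix. The H2A values are uncertain, because these genes are near-identical copies whose reads cannot be assigned to 1 copy with confidence, and the strongest site named Hist1h2ao lay outside the annotated gene. Hist1h2ab also spread widely between replicates, at 1338-fold, 3520-fold and 750-fold.

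On mm10, the Polr2a interval common to all 6 lists spanned chromosome 11, 69733997 to 69735566, within the gene at 69733997 to 69758633. The longer of 2 common Syncrip intervals lay on chromosome 9 from 88482056 to 88482559, and the 1 Nufip2 interval on chromosome 11 from 77686139 to 77686507. For Atn1 the longer of 2 common intervals was on chromosome 6 from 124746020 to 124747989. Exon, intron and UTR annotation was not used here, so the position of sites within the transcript was not analysed.

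Genes with the most sites included long genes of structural and regulatory proteins. Ubr4, a ubiquitin ligase, had 37.3 ± 4.2 sites per list against Input (SD, n = 3), and Dst, a cytoskeletal linker, had 35.0 ± 2.6. Utrn, a dystrophin-related protein gene, had 31.7 ± 2.5 and Syne2, a nuclear envelope protein gene, 30.3 ± 2.5. Their strongest sites were moderate, at 44.1-fold for Ubr4, 27.1-fold for Dst, 23.6-fold for Utrn and 60.6-fold for Syne2.

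Nat10 itself had sites in all 6 lists, but weak ones, with the strongest at 10.6-fold over Input (log2 3.41 ± 0.07, SD, n = 3). No position of a Nat10 site was common to all 6, which also held for Hsf1 and Nr5a2. Of the 8225 genes with sites in all 6 lists, 5593 had a common position. Zp3, a zona pellucida glycoprotein, reached 28.4-fold (log2 4.83 ± 0.29, SD, n = 3), with its strongest site on chromosome 5 from 135980107 to 135980442 (replicate 2), while the 1 interval common to all lists spanned 135985545 to 135985662. The oocyte-secreted growth factor gene Gdf9 had sites over Input in replicates 2 and 3 only, at 7.96-fold and 12.0-fold, although all 3 replicates had sites over IgG (201-fold, log2 7.65 ± 0.28, SD, n = 3). Bmp15, its paralog, had sites over Input in replicates 1 and 2, at 5-fold and 2.04-fold, and over IgG in all 3 (55.2-fold, log2 5.79 ± 0.66, SD, n = 3).

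**Figure D1:**
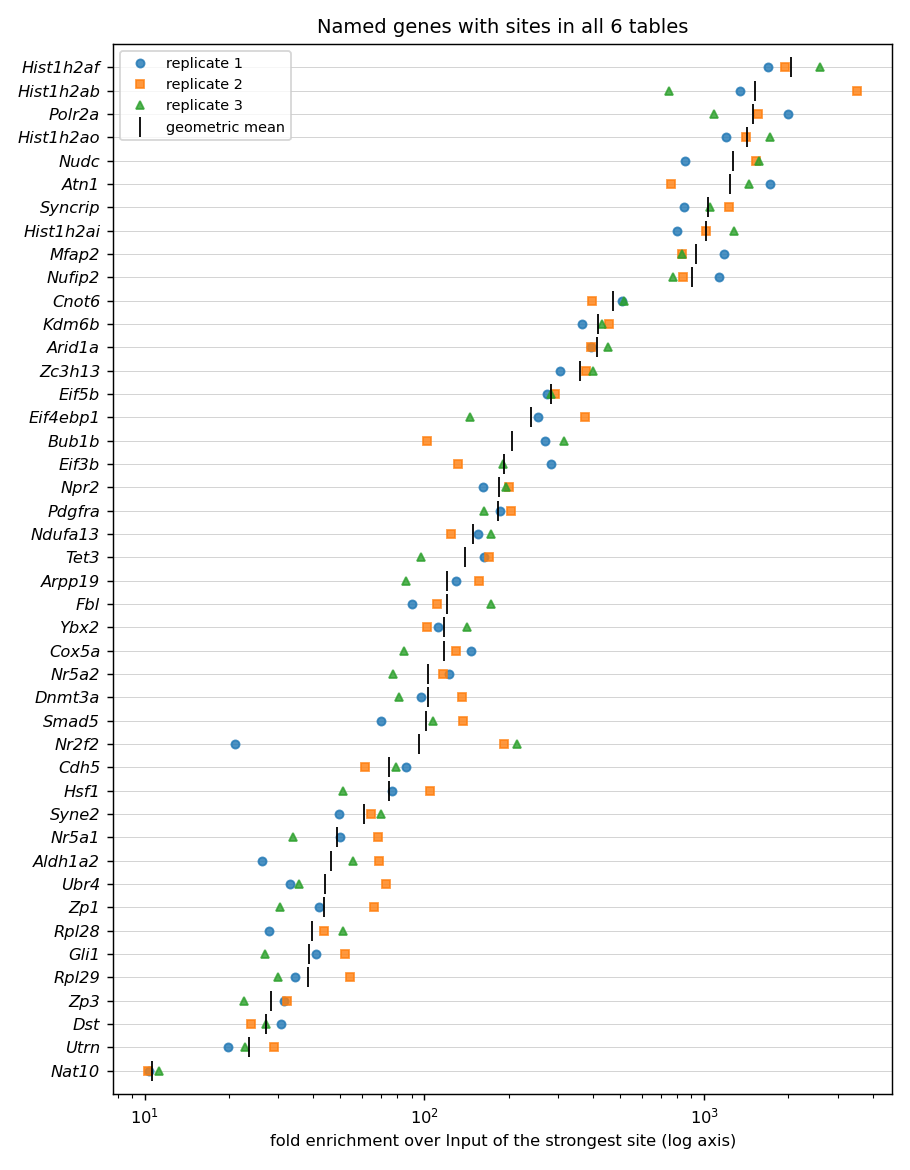
Fold enrichment over Input, on a log axis, of the strongest site of the genes named here that had sites in all 6 lists. Symbols are the 3 replicates and the bar is their geometric mean; Hist1h2af sits at the top at 2047-fold and Nat10 at the bottom at 10.6-fold.

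Over Input, the lists held 39315, 34335 and 39685 sites in replicates 1 to 3, on 11928, 10862 and 11933 genes. Of all 14625 genes listed anywhere, 8711 had a site over Input in all 3 replicates, compared with 7228 from independent lists of the same sizes. The median site was enriched 9.82-fold, 10.0-fold and 9.40-fold. In these lists 35.0%, 34.3% and 36.3% of sites had folds at whole multiples of 0.200, 0.156 and 0.200 (tolerance 0.0075), where chance gives 7.49%, 9.61% and 7.50%, so that part of the folds over Input rest on an Input at its lowest value and are lower bounds. Among the genes named here this held in all 3 replicates for the strongest sites of Ybx2, Dnmt3a, Arpp19 and Cox5a. No site in any list had an authors' false discovery rate of 5% or less, and restricting Input lists to 20% or less lowered the count to 5419 genes, a limit chosen after seeing the data.

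The second comparison set the IP against non-specific IgG, which asks which RNAs were recovered through the antibody. Syncrip was 2848-fold over IgG (log2 11.48 ± 0.28, SD, n = 3), and Cnot6, a deadenylase subunit, 2007-fold (log2 10.97 ± 0.21, SD, n = 3), with 472-fold over Input. Polr2a and Atn1 were 158-fold and 241-fold over IgG. Zc3h13, a subunit of the m6A methyltransferase complex, was 122-fold over IgG and 359-fold over Input. Eif4ebp1, a translation repressor controlled by mTOR, was 58.9-fold over IgG and 241-fold over Input. The 2 kinds of fold were computed by the authors against different libraries, the strongest site over IgG need not be the strongest over Input, and no order between them was tested.

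Against IgG, 47573, 37458 and 48256 sites were listed, on 11941, 10764 and 11906 genes, and 8956 genes had a site in all 3 replicates, compared with 7155 from independent lists. The median site was enriched 32.2-fold, 45.3-fold and 30.3-fold. In these lists 97.0%, 95.4% and 97.0% of sites had folds at whole multiples of 0.375 (tolerance 0.0075), where chance gives 4.0%. The IgG side thus carried the same lowest value at nearly every site, and the fold there followed the height of the IP alone and is a lower bound. Many of the largest enrichments over Input were exceptions. The strongest sites over IgG of Hist1h2af, Hist1h2ab, Hist1h2ao, Hist1h2ai, Polr2a, Nudc, Nufip2, Arid1a and Eif4ebp1 were off these multiples in all 3 replicates. Those of Syncrip and Mfap2 were on them in 1 replicate, and those of Atn1 in all 3. However, the strongest Atn1 site over Input was an interval common to all 6 lists, at 1724-fold, 764-fold and 1450-fold. No Atn1 site exceeded 237-fold, 372-fold and 159-fold over IgG in replicates 1 to 3. With IgG at its lowest value that interval would have the larger fold over IgG, as 0.375 exceeds the steps over Input. IgG was thus above its lowest value at that Atn1 interval. Where a site was off the multiples, IgG was not at its lowest value. The IgG side had a single library and no replicate check. No limit on the false discovery rate was set for the lists against IgG. Their highest score bins had medians of 78.5% to 100%.

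Sites over both controls defined an ac4C gene in the rest of the text. This held for 8225 genes, 56.2% of those listed, including Nat10, Zp1, Zp2, Zp3, Nobox and Kit but not Gdf9, Bmp15, Ddx4 or Dazl. Over Input in all 3 replicates but not over IgG in all 3 were 486 genes, and the reverse held for 731. Independent lists over Input and over IgG would share 5334 genes. The 2 kinds of list contain the same IP libraries and share 1 IgG library, and without counts no simulation of unchanged groups was possible, so part of the excess may come from the shared libraries. Requiring 1 position common to all 6 lists left 5593 genes, and requiring overlap of 50% of both sites left 4734.

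On average 83.6% ± 3.6 of the genes of 1 Input list recurred in another replicate (SD, 6 ordered pairs), compared with 79.1% from independent lists of the same sizes, and 46.8% ± 3.2 of its sites did. Between lists against IgG, 52.0% ± 6.3 of sites recurred. Within 1 IP library, 90.0% ± 1.1 of the sites over Input were also listed over IgG (SD, n = 3), each with the same start and end. Across genes, the log2 fold of the strongest site over Input correlated between replicates with Pearson's r of 0.630 to 0.667 and Spearman's rho of 0.569 to 0.60. These correlations are across genes, which are not independent replicates.

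**Figure D2:**
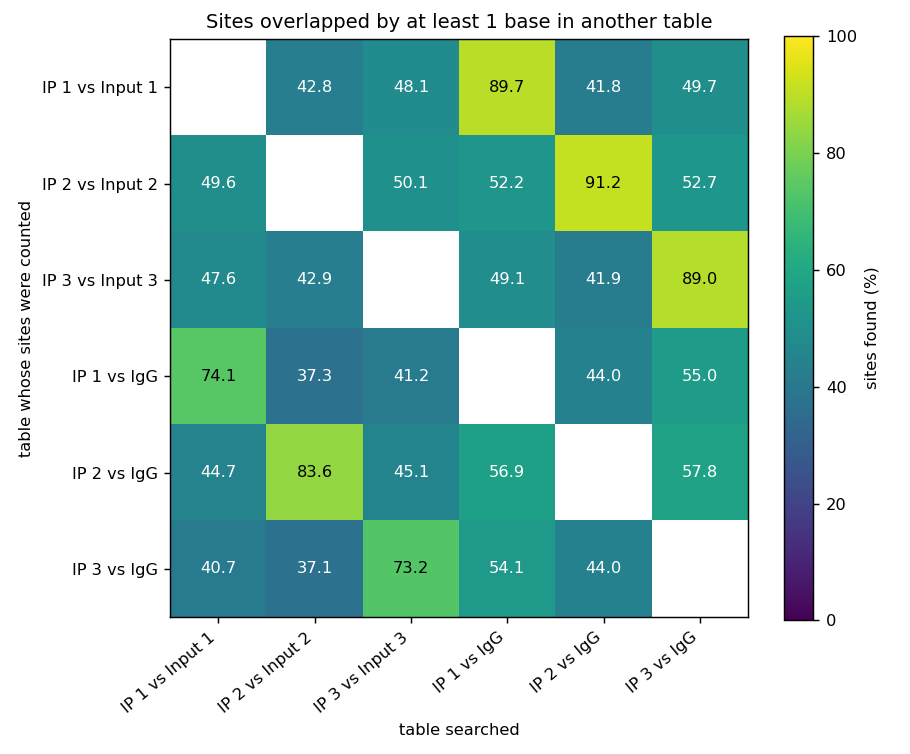
Percent of the sites of each list (rows) overlapped by at least 1 base in each other list (columns), on a color scale from 0 to 100%. The same IP library against its other control gave 73.2% to 91.2%, and different IP libraries gave 37.1% to 57.8%.

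Chromatin and DNA methylation regulators were the list with the highest share of ac4C genes. Of its 46 members, 43 had sites over both controls (93.5%, exact 95% interval 82.1 to 98.6), against 56.2% of all listed genes. Kdm6b, a histone H3 demethylase, reached 416-fold over Input (log2 8.70 ± 0.17, SD, n = 3), and Arid1a, a subunit of the SWI/SNF chromatin remodeler, 413-fold (log2 8.69 ± 0.12, SD, n = 3). The longest of 3 Kdm6b intervals common to all lists spanned chromosome 11 from 69404006 to 69406173, and the longest of 4 for Arid1a chromosome 4 from 133680801 to 133682055. The strongest Arid1a site lay elsewhere, at 133722839 to 133723249 (453-fold in replicate 3). The 3 members outside were Setdb1, with sites in 5 of the 6 lists, Dnmt3l and Ring1. Fisher's exact test, two-sided and adjusted over the 15 lists by Benjamini-Hochberg, gave an odds ratio of 11.2 and p = 5.15e-07. In permutation tests, the adjusted p was 0.003 against random lists matched on gene length, whose mean share was 65.3%, and 0.006 against lists matched on an Input level derived from the folds, with a mean share of 71.9%. The strongest sites of its members averaged 59.8-fold, compared with 35.4-fold in random lists with the same numbers of sites (adjusted permutation p = 0.003).

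Signalling genes of follicle activation came next, with 30 of 35 members of the TGF-beta and PI3K-mTOR list over both controls (85.7%, exact 95% interval 69.7 to 95.2). Eif4ebp1 led them at 241-fold over Input (log2 7.91 ± 0.69, SD, n = 3), followed by Smad5, a transducer of BMP signals, at 101-fold (log2 6.66 ± 0.50, SD, n = 3). Mtor, Tsc1, Tsc2, Foxo3, Kit and Kitl were among the members with sites over both controls. Acvr2a, an activin receptor, missed 1 list. Fisher's exact test gave an odds ratio of 4.68 and an adjusted p of 0.001. The call ended without replicate 3 (adjusted exact p = 0.060) and against length-matched lists (mean share 67.2%, adjusted permutation p = 0.099). It also ended against lists matched on the derived Input level, where the 32 members with a level had a share of 87.5% and the matched lists 72.9% (adjusted permutation p = 0.401). The call held without replicates 1 and 2 (adjusted exact p = 0.019 and 0.009), in 2 of 3 lists (0.044) and at a false discovery rate of 20% or less against Input (77.1%, adjusted exact p = 1.06e-05).

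Stromal and muscle markers also had a high share, 19 of 23 (82.6%, exact 95% interval 61.2 to 95). Pdgfra, a platelet-derived growth factor receptor of fibroblasts, reached 184-fold over Input (log2 7.52 ± 0.16, SD, n = 3), while Nr2f2, a stromal nuclear receptor, varied between 21.0-fold in replicate 1 and 193-fold and 215-fold in replicates 2 and 3. Collagen genes Col1a1, Col1a2 and Col3a1 had sites over both controls, and Dcn had sites over Input in 1 replicate only. The adjusted p of Fisher's exact test was 0.041 with an odds ratio of 3.70, and it rose to 0.132, 0.385 and 0.261 without replicates 1, 2 and 3 in turn and to 0.891 in 2 of 3 lists. At a false discovery rate of 20% or less against Input it was 4.29e-04, with a share of 78.3%. Length-matched lists had a mean share of 57.5% (adjusted permutation p = 0.099), and level-matched lists 73.2% against 81.0% of the 21 members with a level (adjusted permutation p = 0.984).

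RNA modification enzymes and readers had sites over both controls in 23 of 29 cases (79.3%, exact 95% interval 60.3 to 92.0). Zc3h13 reached 359-fold over Input (log2 8.49 ± 0.21, SD, n = 3) and Fbl, the rRNA 2'-O-methyltransferase fibrillarin, 120-fold (log2 6.91 ± 0.48, SD, n = 3). Thumpd1, an adaptor of NAT10 in tRNA acetylation, had sites over Input in replicates 1 and 2 only. Mettl3 and Ythdf2 likewise missed at least 1 list, while Mettl14, Wtap and Alkbh5 did not. With an odds ratio of 2.99, the adjusted p of Fisher's exact test was 0.041, and it was 0.031 without replicate 1, 0.384 without replicate 2, 0.070 without replicate 3, 0.107 in 2 of 3 lists and 0.131 at a false discovery rate of 20% or less against Input. Length-matched lists had a mean share of 58.8% (adjusted permutation p = 0.111) and level-matched lists 72.0% (adjusted permutation p = 0.962).

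Ribosomal protein genes had the lowest share, 18 of the 57 that were listed (31.6%, exact 95% interval 19.9 to 45.2), and another 24 of the 81 had no site in any list. Rpl28 stood highest at 39.6-fold over Input (log2 5.31 ± 0.46, SD, n = 3), at chromosome 7 from 4792990 to 4793409. Rpl29 followed at 38.2-fold, but its strongest site and its common interval lay outside the annotated Rpl29 gene, and ribosomal protein genes in general share reads with processed pseudogenes. The strongest sites of its members averaged 12.2-fold, compared with 19.0-fold in random lists with the same numbers of sites (adjusted permutation p = 0.051). Fisher's exact test gave an odds ratio of 0.358 and an adjusted p of 0.001. Length-matched lists, with a mean share of 36.7%, left no call (adjusted permutation p = 0.683), nor did level-matched lists, with 72.7% against 53.3% of the 15 members with a level (adjusted permutation p = 0.478). At a false discovery rate of 20% or less against Input the adjusted exact p was 0.224. The call held without each replicate in turn (adjusted exact p of 1.12e-04 to 6.35e-04).

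Oocyte genes did not pass the test in any of their lists. The oocyte-secreted and zona pellucida list had 6 of 17 listed members over both controls (35.3%, adjusted p = 0.171 in Fisher's exact test), led by Zp1 at 43.9-fold over Input and Zp3. That share was higher with fewer lists required, at 64.3% without replicate 1, 52.9% without replicate 3 and 76.5% in 2 of 3 lists (adjusted exact p = 1, 0.576 and 1). The share without replicate 2 is not given here. In 2 of 3 lists the share of all genes rose too, to 75.8%, so the list stood near all genes there. At a false discovery rate of 20% or less against Input the list's share was 11.8% (adjusted exact p = 0.124). Their strongest sites averaged 12.2-fold, compared with 23.8-fold in random lists with the same numbers of sites (adjusted permutation p = 0.051). Oocyte transcription and follicle assembly regulators had 7 of 13 (adjusted exact p = 1), among them Ybx2, a germ cell mRNA-binding protein, at 117-fold and the heat shock factor Hsf1 at 74.4-fold. Ddx4, the germ cell helicase, had sites in replicates 1 and 2 only. Maternal effect genes had 24 of 35 (adjusted exact p = 0.288), with Tet3, a DNA dioxygenase active in the zygote, at 139-fold and Dnmt3a, a de novo DNA methyltransferase, at 103-fold; Nlrp4a was in 5 lists. Of the meiotic arrest and maturation genes 21 of 34 had sites over both (adjusted exact p = 0.825; 35.3% at a false discovery rate of 20% or less against Input, adjusted exact p = 1), with the checkpoint kinase gene Bub1b at 206-fold and the phosphatase inhibitor gene Arpp19 at 121-fold, while its paralog Ensa missed 1 list.

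Translation and mRNA decay genes had shares above that of all genes without passing the threshold. Maternal mRNA decay and translational control genes had 27 of 36 over both controls (75%, adjusted p = 0.069 in Fisher's exact test), with Cnot6 at 472-fold over Input (log2 8.88 ± 0.21, SD, n = 3) and Cnot7 in 5 lists. This list passed at a false discovery rate of 20% or less against Input (62.9%, adjusted exact p = 0.009). Translation factors had 23 of 32 (adjusted exact p = 0.166), with Eif5b at 284-fold (log2 8.15 ± 0.05, SD, n = 3), Eif3b at 193-fold, and Eif4e, the cap-binding protein gene, in 5 lists. Nuclear-encoded oxidative phosphorylation genes stood at the overall share, with 34 of 60 (adjusted exact p = 1). Ndufa13 of complex I was 149-fold over Input and Cox5a of complex IV 117-fold, and Ndufb5 missed 1 list.

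Markers of somatic ovarian cells were also present. Granulosa cell markers had 13 of 26 over both controls (adjusted p = 0.825 in Fisher's exact test), with the natriuretic peptide receptor gene Npr2 at 185-fold over Input and the nuclear receptor gene Nr5a2 at 103-fold; Serpine2 was in 5 lists. Theca and steroidogenic markers had 12 of 21 (adjusted exact p = 1), with Nr5a1 at 48.6-fold and the hedgehog effector gene Gli1 at 38.6-fold, and Cyp17a1, the androgen-synthesis enzyme gene, in 5 lists. Endothelial, immune and epithelial markers had 15 of 26 (adjusted exact p = 1), with the endothelial cadherin gene Cdh5 at 74.5-fold and Aldh1a2 at 46.5-fold, and Lyz2 of macrophages in 5 lists. At a false discovery rate of 20% or less against Input the shares of the theca and the endothelial, immune and epithelial lists were 38.1% and 30.8% (adjusted exact p = 1 for both).

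**Figure D3:**
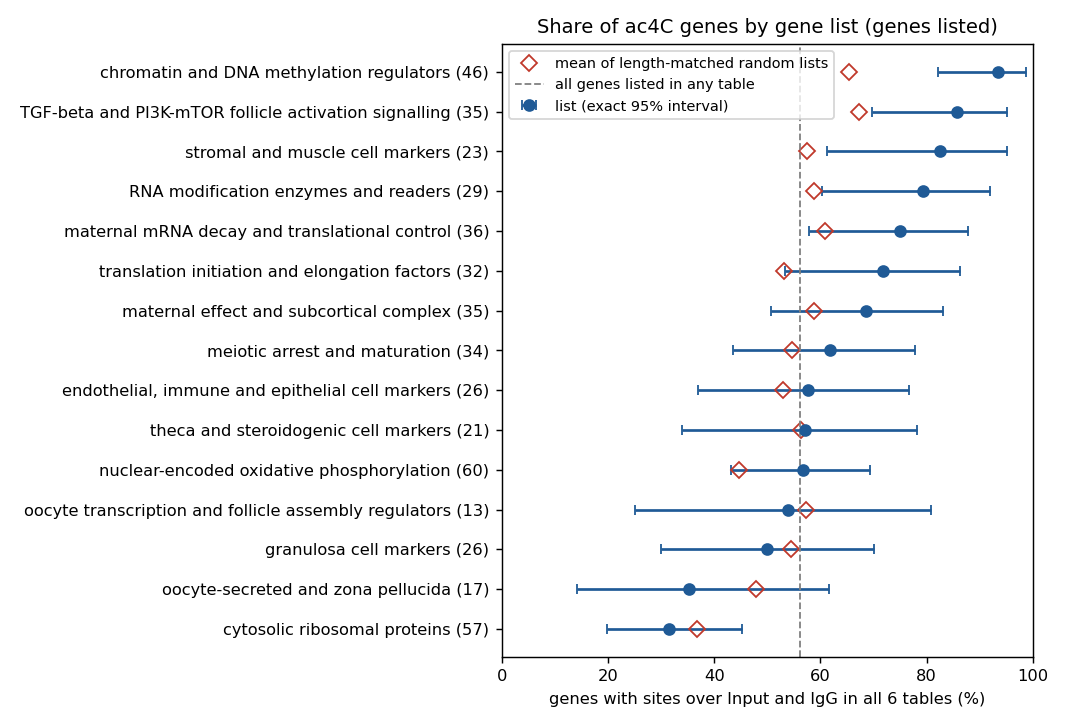
Percent of genes with sites over both controls in each of the 15 lists, with exact 95% intervals as bars and the number of listed members in parentheses. Open diamonds are the mean of length-matched random lists and the dashed line is the 56.2% of all listed genes; chromatin regulators lie highest at 93.5% and ribosomal proteins lowest at 31.6%.

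Gene length went with the calls. With genes ordered by genomic length in 10 bins of equal size, 33.8% of the shortest (median 2.62 kb) had sites over both controls, compared with 71.4% in bin 9 (median 95.1 kb) and 69.4% in bin 10 (median 214 kb). In the authors' lists the false discovery rate fell with the score against Input, from a median of 59.7%, 49.8% and 40.2% in the lowest of 10 score bins to 18.4%, 10.7% and 15.2% in the highest. Against IgG it went the other way, from 5.32%, 7.47% and 5.32% to 100%, 78.5% and 100%.

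**Figure D4:**
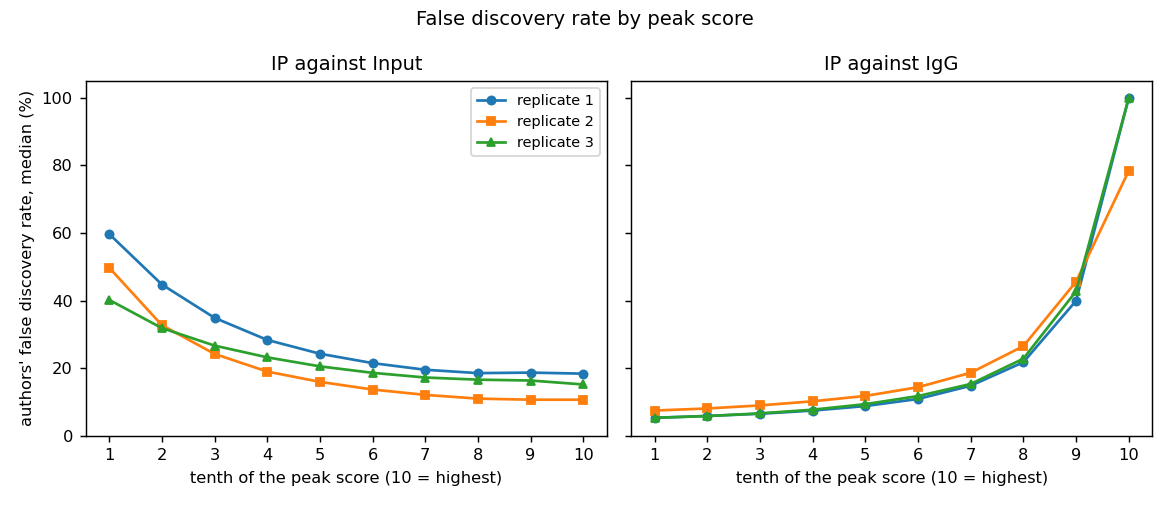
Median of the authors' false discovery rate, in percent, by bin of the peak score (10 bins of equal size per list) for the IP against Input (left) and against IgG (right), 1 line per replicate. The highest bin reached 10.7% to 18.4% against Input and 78.5% to 100% against IgG.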

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

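The sites below lie on chromosome Y, although the labelled tissue, ovary, has no chromosome Y. They are counted in the totals of the lists, and no comparison of the report is about them. The lists against Input held 6, 5 and 7 sites on chromosome Y in replicates 1 to 3, and those against IgG held 5, 4 and 6. All of them carried the gene names Erdr1 or Gm21857, chosen for naming after the values were seen. The RefSeq table of the same assembly places Erdr1 on chromosome X and lists Gm21857 as another name of the pseudogene Mid1-ps1.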

How the results depend on the processing

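Limits on the false discovery rate, matched random lists, 16-fold over IgG, 2 of 3 lists for a single control and the median site were chosen after the data were seen; the other settings were planned. Counts of ac4C genes stayed within 1.5 times of 8225 at a score of at least 75 (7809), at 4-fold (7867), in 2 of 3 lists (11092), at 16-fold over IgG (7618), over 1 control alone and with 1 common position; without single replicates they were 8974 to 9585. They moved to 5259 at a false discovery rate of 20% or less against Input, where genes over Input fell from 8711 to 5419. They moved to 4734 when sites had to overlap by 50% of both. Both settings keep fewer sites by construction. List shares printed at that false discovery rate belong with the lower count of 5259 genes, not with the 56.2% of the main setting. Shares without a replicate or in 2 of 3 lists belong with the higher counts. Site agreement between replicates went from 46.8% to 37.1% with that overlap rule, and was 46.1% at a score of at least 75. The number of gene lists past Fisher's exact test was 5, and 2 to 4 without single replicates (4, 3 and 2 without replicates 1, 2 and 3), 3 in 2 of 3 lists, 3 at an adjusted p of 0.01, and 1 against lists matched on gene length and 1 on the derived Input level; the cause was not tested. Chromatin regulators passed in each setting computed for single lists (score, fold, false discovery rate, replicates, both matchings), with adjusted p between 3.33e-09 and 0.006. With the median site in place of the strongest, 44 of 61 named genes moved by more than their SD; leaving out 1 of 3 replicates cannot do so by arithmetic and tests nothing here. No list changed direction while past the threshold.

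No paired analysis was possible because each list sets 1 IP library against 1 control and holds no values of single libraries. For the same reason other normalizations, a filter on low counts or depth and a test without the replicate number were not run. For sites and genes the score limit stood in for an adjusted p of 0.01, as no site had a false discovery rate of 5% or less. Neither a background of uncalled genes nor any setting for positions in the transcript was run. Without depths, a missing site in Gdf9, Bmp15 or Ddx4 is not shown to be absent.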

Other observations

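The tests against matched lists, the pathway tests and the test of a constant number of IgG peaks were chosen after the results were seen. Of 277 KEGG pathways named in the authors' files and tested over 4991 annotated genes, 61.9% of which were ac4C genes, 43 had a higher and 23 a lower share (Fisher's exact test, Benjamini-Hochberg over the 277). Matched lists were drawn for these 66 pathways, with adjustment over the 66 and, for the level, over members with a derived level only. Protein processing in the endoplasmic reticulum had 129 of 155 genes over both controls (83.2%, adjusted permutation p = 0.002 against both length-matched and level-matched lists). Focal adhesion had 140 of 179 (78.2%), insulin signalling 92 of 117 (78.6%), mTOR signalling 46 of 56 (82.1%) and Notch signalling 36 of 44 (81.8%), all past both matched tests. Oocyte meiosis, at 73 of 96 genes, passed against length-matched lists (adjusted permutation p = 0.027) but not against lists matched on the derived Input level (adjusted permutation p = 0.142), and RNA degradation, at 56 of 73, did the same (0.010 and 0.221).

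Among pathways with a lower share, neuroactive ligand-receptor interaction had 30 of 100 listed genes over both controls, olfactory transduction 20 of 62 and allograft rejection 2 of 21. Retinol metabolism had 6 of 25, peroxisome 33 of 71 and the broad group of metabolic pathways 535 of 959 (55.8%), all past both matched tests. Steroid hormone biosynthesis, with 6 of 22, passed against length-matched lists (adjusted permutation p = 0.010) but not level-matched ones, for which 17 genes had a level (35.3% against 58.9%, adjusted permutation p = 0.073). The Ribosome pathway, with 42 of 102, missed the threshold against length-matched lists (adjusted permutation p = 0.281), and its 58 genes with a level passed against level-matched ones (55.2% against 74.2%, adjusted permutation p = 0.009). After both matchings 23 higher and 15 lower pathways were left, but 7 and 6 with adjustment over all 277. Of those named here, protein processing, focal adhesion, neuroactive ligand-receptor interaction, allograft rejection and metabolic pathways passed that adjustment, and the others did not.

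Against IgG, the strongest sites had the highest false discovery rates. IgG reads at those positions were not the reason for most of them, since at most 9.24% of the sites in the highest of 10 score bins lay off the IgG step. A ceiling of the score was argued against by sites scoring under 1000, where score and rate still rose together (rank correlation across sites of at least 0.999986). The product of the rate and the number of listed sites at or above each score varied by 1.29 times at most over the 10 score bins, against 24.0 to 42.6 times in the lists against Input, which is consistent with a near-constant number of high-scoring IgG peaks elsewhere, if the rate is the ratio of control to IP peaks, as the form of the files suggests. In replicates 1 and 3 the median rate of the highest bin was 100%, which was also the highest rate in those lists. If the rate is capped there, the product is understated. The lists also hold only a part of the called peaks. No biological explanation was tested.

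Site positions recurred more within 1 IP library than between IP libraries, which shared 52.1% as many sites. That ratio decides nothing about coverage particular to each library, since recurring sites within 1 library had the same start and end, as calls on the same IP reads, so it stays open. Lists that share the IgG library overlapped by 5.11 percentage points more than lists with separate Inputs. This cannot tell whether a control shapes positions, because IgG was at its lowest value at nearly every site. The lists against IgG were also larger, with 44429 sites on average against 37778. The values do show that recurring sites of 1 IP library kept their start and end under either control. In 3 of 3 pairs of IP libraries the shared bases exceeded the highest of 100 rotations within each gene's listed bases. The shares were 48.2%, 55.5% and 59.5%, against 43.2%, 52.8% and 53.9% in the highest rotations. However, 14.1% to 18.4% of sites over Input had the same start and end in another IP library. In the lists 4242 intervals started 1 base before the RefSeq start of their gene and 4549 ended at its RefSeq end. Rotation does not keep such edges, so the excess cannot tell shared IP signal from shared gene edges. No group in the design separates a biological source of the difference between libraries, which stays open.

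Gene lists differed in their share of ac4C genes. Neither genomic gene length nor the derived Input level accounted for the chromatin regulators. They were the 1 list that passed against length-matched lists and the 1 that passed against level-matched lists. The derived level exists only for genes with the same interval listed over both controls in at least 1 replicate. It is also linked to the fold over Input, so it cannot exclude mRNA abundance. Abundance, mature mRNA length, sequence composition and a real preference of acetylation stay open, and the last 3 were not tested. For ribosomal proteins gene length is a candidate explanation, as length-matched lists closed 79.9% of the gap to all genes. Gene length was argued against for the stromal and RNA modification lists, where length-matched lists closed 0.588% and 6.47% of the gap (unadjusted permutation p = 0.018 and 0.030), while the derived Input level is a candidate explanation, as level-matched lists closed 63.9% and 63.4%; chance stays open too, at adjusted permutation p of 0.099 and 0.111 against length-matched lists. For the TGF-beta and PI3K-mTOR list, length-matched lists closed 34.8% and level-matched lists 47.9% of the gap with no call left in 35 genes, so length, level and a real difference cannot be told apart there.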
